A study of Arabidopsis thaliana with 12 samples.

How the data were processed

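RNA was sequenced from 12 pools of Arabidopsis seedlings, 3 per combination of genotype (wild type or irr) and treatment (water or 1 µM AtPep1). Per the labels' protocols, seedlings aged 7 to 10 days were moved to liquid medium, about 15 to a well, treated 3 h later for 24 h in constant light, and their RNA was extracted with a plant RNA kit, treated with DNase and sequenced as paired ends, with 20 M raw reads (M for 1e+06) stated per sample. Nothing in the labels says whether replicates came from separate cultures or days, so p-values measure only the spread between these samples, which may be technical. The values are FPKM, fragments per kilobase of gene and per M fragments, as deposited by the authors in 1 table of 32846 genes with 1 column per library. The aligner, the counting tool, the genome build, the annotation and any filter are not given in the sources used here, and for this reason no coordinates are printed. Column sums ran from 762741 to 828006. The TAIR10.1 reference was used for gene names and for which genes lie beside each other, and 31912 identifiers matched it. The table also has 168 numbered identifiers without a locus name, and 6656 genes at 0 in every library.

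Depth was recovered from the steps in the values, since a gene's FPKM is a whole number of reads times a constant set by its length and the library total. With the totals found from 20906 genes of a single transcript, all 26190 genes above 0 gave whole reads in every library, within 0.05 of a read and at lengths of up to 20000 bases. Wrong totals gave whole reads for 0% of 300 genes, all of which passed the expression filter described below. The method was tested on simulated data, where 12 of 12 totals and 100% of 400 lengths were recovered. The 400 genes had more than 20 reads in every simulated library, so recovery of lengths was not tested for genes with fewer reads. The totals are what was assigned to genes, with a median of 20.2 M, and are called reads here. That is above the 20 M raw reads stated per sample, which the sources used here do not explain. Whether the unit is a read or a fragment is not known. Reads are not independent molecules, so depth sets counting error only.

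Genes with an FPKM of at least 1 in at least 3 libraries were kept, 18177 in all. Values were taken as log2(FPKM + 1), with a pseudocount of 1, and fitted by limma 3.58.1 in R 4.3.3 with 1 mean per group over all 12 libraries, 8 residual degrees of freedom and a mean-variance trend. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a contrast and a threshold of 0.05. The contrasts were Pep1 against water in each genotype, irr against wild type in each treatment, and their interaction. The fit was tested on simulated data for Pep1 in wild type over 17840 genes, where 76% of 100 genes changed by a factor of 2 and 95% of 100 changed by a factor of 4 were called. Of all 188 calls 3.72% were unchanged genes, and a comparison with no change gave 0 calls. A further list of 20 genes was shifted in the simulation, and these do not count as unchanged. Genes were drawn independently, with the same spread in every group, so correlated genes and groups of unequal spread were not tested.

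The 19 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives other than the one named as added. Of 329 list entries, 8 were dropped because identifier and symbol disagreed in the reference (PROPEP7, SARD4, IPMDH1, UGT74C1, C3H1, UGT75C1, PRX4 and PRX62). The lists were tested by camera with a preset inter-gene correlation of 0.01 and adjustment over the lists of a contrast. None of the lists called at the preset correlation was called with an estimated correlation, in any of the 5 contrasts. Estimated correlations ran from 0.145 for root markers to 0.842 for aliphatic glucosinolates, above the preset in every list. The p values at the preset correlation may therefore be too small. The root and low-oxygen lists mark tissue make-up and handling. The size of the Pep1 response was tested by fry on the interaction, over genes with an adjusted p under 0.05 and an absolute log2 value of at least 1 for the mean Pep1 effect, a contrast orthogonal to the interaction.

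Named genes follow a rule. AT3G23900 and CPK28 come first. In each comparison of 2 groups come up to 6 rises and up to 6 falls, those with the largest fold change among genes with an adjusted p under 0.05, a mean of at least 2 FPKM and no overlap between replicates. From each list come up to 4 members that passed with the largest change, or up to 2 with the highest mean where none passed. For the interaction come the 5 smallest p values. Not every gene so chosen is printed.

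Alternatives were pseudocounts of 0.1 and 5, no filter, a filter on a mean of at least 5 FPKM, equal library medians, quantile normalization, the replicate number as a block, no trend, library quality weights, a fit of only the 2 groups compared, and leaving out each library. Voom on the recovered reads was added after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots. No column of the table was left out, and no library was a copy of another.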

Results

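Messenger RNA levels were measured in whole seedlings of Arabidopsis thaliana, accession Columbia, in a design that crosses 2 genotypes with 2 treatments. The genotypes were wild type and the mutant irr, also labelled rrm. IRR is known from the published study as a gene for an immunoregulatory protein with an RNA recognition motif. The treatment was 1 µM AtPep1, a peptide released from a precursor protein on wounding or attack and perceived by the receptor kinases PEPR1 [AT1G73080] and PEPR2, or water. The labels of the controls call them untreated, while the protocol text names water, and they are called water libraries here. Each of the 4 groups holds 3 libraries, 12 in all. Library totals, recovered from the steps between low values, ran from 17.4 M to 28.6 M reads in 11 libraries, and irr water replicate 3 held 56.5 M. A single read in a gene of 1 kb was worth between 0.0177 and 0.0574 FPKM. Spearman's rho across genes between libraries of 1 group lay between 0.957 and 0.988, where genes are not independent replicates. The lowest value belonged to irr Pep1, whose median SD per gene on the log2 scale was 0.19, against 0.12 in wild type with Pep1. In the text, group values are mean FPKM ± SD with n = 3, and fold changes are log2 values on the log2(FPKM + 1) scale ± SE, which understates changes of low genes.

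The locus known for IRR, AT3G23900, was measured first as a check of the genotype labels. Its level was 12.8 ± 1.93 FPKM in wild type and 11.95 ± 0.72 in irr under water, and 11.6 ± 0.995 and 11.2 ± 0.573 with Pep1. The genotype difference was -0.08 ± 0.11 under water (limma adjusted p = 0.715) and -0.04 ± 0.11 with Pep1 (adjusted p = 0.883). The level of this gene therefore does not separate the libraries labelled irr from wild type. A gene-level value cannot check a mutation that leaves transcript reads in place, and every genotype direction given here rests on the labels. CPK28 [AT5G66210], a calcium-dependent protein kinase that limits immune signalling and a known splicing target in the published work, stood at 11.2 ± 1.46 FPKM in wild type and 15.7 ± 1.28 in irr under water. With Pep1 it stood at 12.9 ± 0.866 and 23.1 ± 6.67. Its genotype difference with Pep1 was 0.75 ± 0.18 and missed the threshold (adjusted p = 0.0608), and gene-level values do not show its splice forms.

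**Figure D1:**
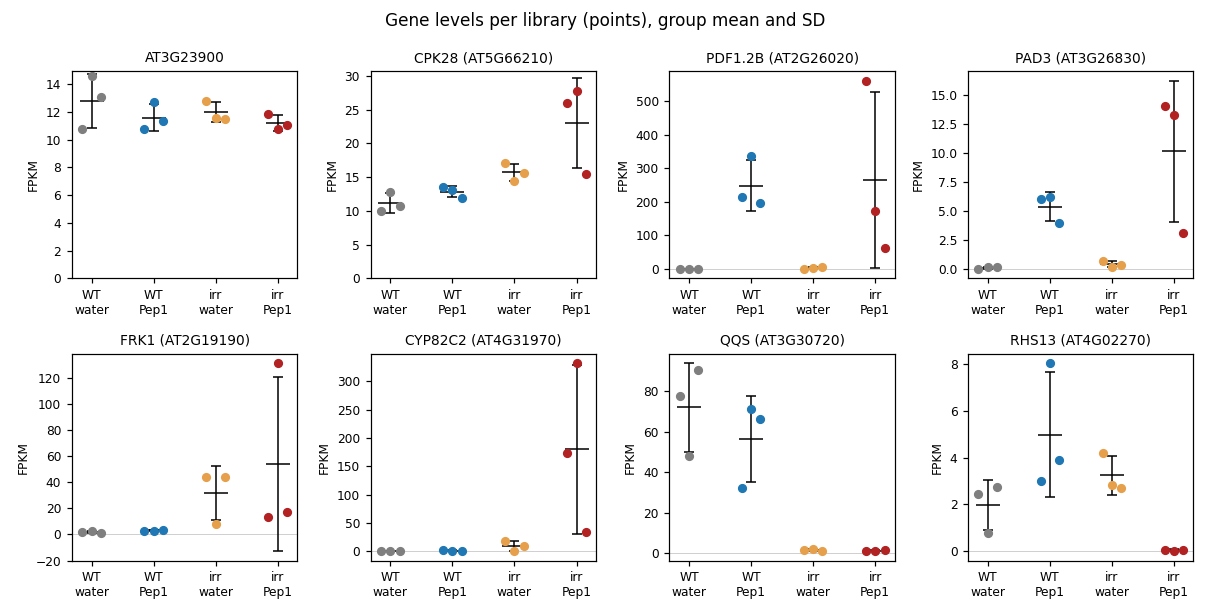
FPKM (vertical axes, linear) of 8 genes in the 4 groups (horizontal axes), with a point per library, the group mean as a horizontal bar and the SD as whiskers, n = 3 per group. QQS stood near 1.69 FPKM in irr and 72.1 in wild type under water, the group means of AT3G23900 lay between 11.2 and 12.8, and the irr Pep1 libraries were widely spread for PDF1.2B, FRK1 and CYP82C2.

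The first comparison asked which genes respond to Pep1 in wild type after 24 h. Genes for antimicrobial proteins were among those that rose most. PDF1.2B [AT2G26020], a plant defensin, went from 0.343 ± 0.153 to 248 ± 76.7 FPKM (7.50 ± 0.71, limma adjusted p = 0.00119). The related defensin genes PDF1.3 [AT2G26010] and PDF1.2A [AT5G44420] rose by 6.96 ± 1.04 and 6.12 ± 0.92, and PDF1.2C [AT5G44430] was listed at 0 in all 3 water libraries and at 5.27, 17.4 and 44.0 FPKM in those with Pep1. These defensin genes are close copies, so the division of reads among them is uncertain. ORA59 [AT1G06160], a transcription factor that joins jasmonate and ethylene signals and acts on the defensin genes, rose from 2.52 ± 0.54 to 29.6 ± 5.7 FPKM (3.12 ± 0.22, adjusted p = 0.000197). AT4G33720, of the family of pathogenesis-related secreted proteins, went from 6.72 ± 6.67 to 485 ± 95.1 FPKM. Peroxidase genes rose as well, with PRX52 [AT5G05340] at 5.18 ± 0.68 and Prx37 [AT4G08770] at 4.93 ± 0.61.

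Of the 13 measured antimicrobial genes, 6 rose and 0 fell over all genes tested, and 9 rose adjusted over the list alone. The list was called higher by camera (median 2.23, adjusted p = 7.54e-08). With an estimated correlation its adjusted p was 0.366, and fry, which asks whether the list itself moves, gave an adjusted p of 0.00508. Among the 11 ethylene genes only ORA59 rose, and 6 rose adjusted over the list alone (camera adjusted p = 0.000101, or 0.581 with an estimated correlation). Of 16 genes for glutathione transferases and peroxidases, 3 rose (8 over the list alone). They were PRX52, GSTF3 [AT2G02930] at 1.99 ± 0.33 and GSTF2 [AT4G02520], which went from 252 ± 39.3 to 813 ± 148 FPKM (camera adjusted p = 0.000278, or 0.581 with an estimated correlation).

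PAD3 [AT3G26830], which makes the last step to the phytoalexin camalexin, rose from 0.14 ± 0.0857 to 5.39 ± 1.26 FPKM and was the 1 member of 19 to rise in the camalexin and indole glucosinolate list (2 over the list alone). PAL4 [AT3G10340], an entry enzyme of phenylpropanoid synthesis, rose from 2.8 ± 0.15 to 9.93 ± 2.44 FPKM and was the 1 of 15 in its list (7 over the list alone). The protein kinase MPK3 [AT3G45640] and the ubiquitin ligase PUB25 [AT3G19380] rose among 25 genes of pattern perception, by 0.86 ± 0.19 and 0.37 ± 0.09 (3 over the list alone). Camera called these 3 lists higher, at adjusted p values of 3.92e-05, 0.00289 and 0.001. It also called higher the 17 pattern-induced markers (median 0.59, adjusted p = 0.00546) and the 21 jasmonate genes (median 0.29, adjusted p = 0.000837), of which 0 passed over all genes and 4 and 7 over the list alone. With an estimated correlation, all 5 of these lists had an adjusted p of 0.581.

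The 39 nuclear photosynthesis genes were called lower as a list (median -0.32, adjusted p = 3.92e-09, or 0.581 with an estimated correlation), although 0 of them passed singly. LHCB1.1 [AT1G29920], a light-harvesting protein gene, had a value of -0.71 ± 0.22 (adjusted p = 0.0963). The 10 other lists were not called, among them the salicylic acid genes (median 0.19, adjusted p = 0.446) and the Pep1 precursors and receptors (median 0.03, adjusted p = 0.988). Their medians were -0.46 for aliphatic glucosinolates, -0.10 for flavonoids, -0.17 for cell division, 0.29 for auxin, -0.28 for abscisic acid and 0.04 for splicing factors. Root markers had a median of 0.58 (adjusted p = 0.0557) and low-oxygen markers of 0.34 (adjusted p = 0.22). Among genes with a mean of at least 2 FPKM, PME5 [AT5G47500] fell most, from 16.4 ± 6.33 to 1.46 ± 0.67 FPKM (-2.79 ± 0.35). Its product name gives only a family, the pectin lyase-like superfamily. The next largest falls were those of AT2G27402 (-2.44 ± 0.35), AT3G45160 (-2.42 ± 0.52), MLP28 [AT1G70830] (-2.25 ± 0.28), BGLU18 [AT1G52400], a beta-glucosidase (-2.21 ± 0.29), and AT4G15620 (-2.08 ± 0.31).

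In all, 630 of 18177 genes changed in wild type (limma, Benjamini-Hochberg, 0.05), 387 rising and 243 falling, and 165 by an absolute log2 value of at least 1. With library medians made equal, 313 rose and 324 fell, and the count was 2025 with library quality weights, 1974 in a fit of only the 2 groups and 407 without an expression filter. The count was 105, 127, 137, 107 and 169 without WT water replicate 1, WT water replicate 2, and WT Pep1 replicates 1, 2 and 3. It was 970 and 1048 without irr Pep1 replicates 2 and 3, which enter through the shared estimate of the spread.

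The same question was asked of the libraries labelled irr. Here too PDF1.2B rose most, from 3.56 ± 3.38 to 265 ± 262 FPKM (5.69 ± 0.71, adjusted p = 0.0101). CYP82C2 [AT4G31970], a cytochrome P450 of indole metabolism, stood at 9.89 ± 8.67 and 180 ± 149 FPKM (3.98 ± 0.80, adjusted p = 0.035). PAD3 rose by 2.74 ± 0.39, the transcription factor MYB122 [AT1G74080] by 2.36 ± 0.34 and CYP79B3 [AT2G22330], an early enzyme of indole glucosinolate synthesis, by 1.73 ± 0.35. These 4 were the members of the camalexin and indole list that rose, and 11 of 19 rose adjusted over the list alone (camera adjusted p = 1.14e-11, or 0.625 with an estimated correlation). Prx37, the dirigent protein DIR5 [AT1G64160] and the peroxidase AT4G11290 rose by 3.24 ± 0.61, 2.75 ± 0.54 and 2.61 ± 0.43.

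Of the 13 antimicrobial genes 2 rose, PDF1.2B and PR4 [AT3G04720] (1.46 ± 0.30), and over the list alone 8 rose and 1 fell (camera adjusted p = 0.000158, or 0.625 with an estimated correlation). ORA59 rose from 8.23 ± 2.06 to 28.4 ± 7.43 FPKM and was the 1 of 11 ethylene genes to pass, and PUB25, at 0.54 ± 0.09, the 1 of 25 genes of pattern perception. These 2 lists were called higher (adjusted p = 0.0048 and 0.000228). So were the pattern-induced markers (median 0.42), the jasmonate genes (0.31), the phenylpropanoid genes (0.49) and the glutathione transferases and peroxidases (0.72), in which 0 passed over all genes and 1, 1, 2 and 2 over the list alone. With an estimated correlation these 6 lists had an adjusted p of 0.625. HAI1 [AT5G59220], a protein phosphatase of abscisic acid signalling, rose by 1.16 ± 0.17, and LBD41 [AT3G02550], a low-oxygen marker, by 0.69 ± 0.12. Their lists, of 13 and 7 genes with 1 passing in each, were called higher (medians 0.14 and 0.22, adjusted p = 0.0407 and 0.0139). With an estimated correlation both had an adjusted p of 0.625. Root markers were not called as a list (median -0.07, adjusted p = 0.135), with 1 of 11 falling and 2 over the list alone. Among genes that fell, RHS13 [AT4G02270], a root hair gene, went from 3.24 ± 0.828 to 0.0494 ± 0.0428 FPKM (adjusted p = 0.0176) and the root marker EXP7 [AT1G12560], an expansin of root hairs, from 4.36 ± 1.51 to 0.486 ± 0.285. The extensin-like AT3G54580 fell by 1.83 ± 0.37, the secreted protein AT5G57625 by 1.85 ± 0.35, the germin GER3 [AT5G20630] by 1.79 ± 0.33 and MLP28 by 1.78 ± 0.28.

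In irr, 362 genes changed with Pep1, 134 rising and 228 falling, and 106 by at least 1 on the log2 scale. More genes rose than fell without irr Pep1 replicate 3 (954 and 451) and with library quality weights (568 and 473). Camera called 10 of the 19 lists, all higher, and with an estimated correlation 0 of them. The count was 0 in a fit of only the 2 groups (limma, 2263 at an unadjusted p under 0.05) and 1041 with quality weights. It was 194 without an expression filter, 223 without a variance trend and 147 with the replicate number as a block. No gene was called without irr water replicate 2 (limma, 2160 at an unadjusted p under 0.05), and 109, 20, 13 and 1405 were called without irr water replicate 1 and irr Pep1 replicates 1, 2 and 3. The count was 198 without WT water replicate 1, and 143, 157 and 183 without WT Pep1 replicates 1, 2 and 3.

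The comparison of genotypes under water asked whether transcript levels differ between irr and wild type without Pep1. No second irr allele or complemented line is among the groups, so the mutation cannot be told apart from other differences between the lines. FRK1 [AT2G19190], a receptor kinase gene used as a marker of pattern-triggered immunity, stood at 1.73 ± 0.789 FPKM in wild type and 31.7 ± 20.8 in irr (3.28 ± 0.77, limma adjusted p = 0.039). The camalexin enzyme gene CYP71A12 [AT2G30750] was higher by 3.86 ± 0.64 and PAL1 [AT2G37040], of phenylpropanoid synthesis, by 2.61 ± 0.53. GSTF7 [AT1G02920] and GSTF6 [AT1G02930], neighbouring genes of near-identical sequence whose reads may be divided uncertainly, were higher by 3.44 ± 0.56 and 3.31 ± 0.59. A further set of genes separated the genotypes with little spread. STP9 [AT1G50310], a sugar transporter, stood at 0.0577 ± 0.0148 FPKM in wild type and 12.5 ± 3.2 in irr, and QQS [AT3G30720], a gene that acts on starch content, at 72.1 ± 21.8 and 1.69 ± 0.474 (-4.73 ± 0.29, adjusted p = 1.4e-05).

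Of 15 salicylic acid genes 5 were higher (8 over the list alone), including the regulators CBP60G [AT5G26920] (2.29 ± 0.44), WRKY70 [AT3G56400] (1.76 ± 0.40), SARD1 [AT1G73805] (1.43 ± 0.32) and FMO1 [AT1G19250] (1.54 ± 0.31), which acts in systemic resistance. Of 11 ethylene genes 6 were higher (9 over the list alone), among them ERF5 [AT5G47230] at 1.48 ± 0.29 and ORA59 at 1.38 ± 0.22. Of 13 antimicrobial genes 3 were higher (7 over the list alone), namely CHI [AT2G43570], PR4 and TI1 [AT2G43510], at 1.87 ± 0.38, 1.79 ± 0.30 and 1.70 ± 0.38. Camera called these 3 lists higher, with adjusted p values of 3.43e-06, 6.43e-07 and 1.52e-05, all of them 0.424 with an estimated correlation. They were also the 3 lists that passed fry (adjusted p = 0.0311 for each).

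Of 17 pattern-induced markers 4 were higher (12 over the list alone), with WRKY33 [AT2G38470] at 1.89 ± 0.39, WRKY53 [AT4G23810] at 1.58 ± 0.37 and WRKY28 [AT4G18170] at 1.27 ± 0.29 beside FRK1. Of 16 glutathione transferases and peroxidases 6 were higher (9 over the list alone), and of 19 camalexin and indole genes 4 (over the list alone 9 higher and 1 lower). These 3 lists had camera adjusted p values of 3.75e-07, 1.83e-05 and 2.1e-06, and each 0.437 with an estimated correlation. Of 25 genes of pattern perception 3 were higher (12 over the list alone), the ubiquitin ligase PUB23 [AT2G35930] (1.78 ± 0.38), the receptor-like kinase SOBIR1 [AT2G31880] (1.07 ± 0.21) and CPK6 [AT2G17290] (0.64 ± 0.15), with a camera adjusted p of 3.75e-07, or 0.437 with an estimated correlation. The jasmonate list, with JAZ1 [AT1G19180] (2.04 ± 0.44) and ACX1 [AT4G16760] (0.80 ± 0.17) passing, and the phenylpropanoid list, with PAL1 and C4H [AT2G30490] (1.46 ± 0.37), were called higher at adjusted p values of 0.00306 and 0.00575, both 0.44 with an estimated correlation. Over the list alone 3 of 21 and 6 of 15 were higher.

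The lists called lower under water had 0 members passing over all genes. Photosynthesis genes had a median of -0.30 over 39 genes (adjusted p = 6.92e-08), cell division genes of -0.22 (adjusted p = 0.00716) and abscisic acid genes of -0.32 (adjusted p = 0.0195), each with an adjusted p of 0.44 with an estimated correlation. Over the list alone the abscisic acid genes went both ways, 2 higher and 2 lower, and 0 passed in the 4 other lists called lower. Aliphatic glucosinolate genes had a median of -1.08 (adjusted p = 0.0113, or 0.437 with an estimated correlation) and splicing factors of -0.06 (adjusted p = 0.0195, or 0.476 with an estimated correlation). The low-oxygen markers were not called, with a median of 0.12, a mean of -0.03 and a camera direction of lower (adjusted p = 0.856), and neither were the root markers (median 0.14, adjusted p = 0.755).

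Further rises were those of AT4G12500 and AT4G12490, of the lipid-transfer protein family (5.04 ± 0.94 and 4.28 ± 0.89), the extensin-like AT1G26240 (4.08 ± 0.56) and the peroxidase AT1G49570 (3.58 ± 0.56). Beside QQS the largest falls were AT4G01980, from 6.5 ± 1.01 to 0.0584 ± 0.101 FPKM, the transporter AT4G34950 (-2.73 ± 0.31), LEA18 [AT2G35300] (-2.69 ± 0.56), SADHU3-2 [AT3G42658] (-2.07 ± 0.39) and AT1G75900 (-1.94 ± 0.38). PROPEP3 [AT5G64905], a precursor of a Pep peptide, was at 0.587 ± 0.286 and 8.68 ± 6.82 FPKM and missed the threshold (2.29 ± 0.70, adjusted p = 0.0852).

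Under water 713 genes differed between genotypes, 538 higher and 175 lower in irr, and 263 by at least 1 on the log2 scale. With library medians made equal 433 were higher and 289 lower, and after quantile normalization 466 and 327. Without an expression filter 267 genes differed, with a pseudocount of 5 there were 469, and with the replicate number as a block 389. The count was 46, 97 and 324 without WT water replicates 1, 2 and 3, and 139 and 67 without irr water replicates 1 and 3, the latter the library of 56.5 M reads, in which chloroplast-encoded genes took 3.09% of reads against 0.886% to 1.53% in the others. It was 357, 462 and 423 without WT Pep1 replicates 1, 2 and 3, and 1431 and 1330 without irr Pep1 replicates 2 and 3.

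With Pep1 present, genes of indole defence compounds were among those that differed most between genotypes. CYP82C2 stood at 0.962 ± 0.906 FPKM in wild type and 180 ± 149 in irr (6.12 ± 0.80, adjusted p = 0.00719). CYP71A12, CYP79B2 [AT4G39950] and CYP81F2 [AT5G57220] were higher by 3.96 ± 0.64, 3.20 ± 0.67 and 3.08 ± 0.64. Of the 19 camalexin and indole genes 6 were higher and 16 over the list alone (camera adjusted p = 2.46e-13, or 0.344 with an estimated correlation). AT1G26240 stood at 0.779 ± 0.257 FPKM in wild type and 106 ± 72.6 in irr (5.59 ± 0.56), and the peroxidase PER4 [AT1G14540] and the berberine bridge enzyme AT1G26380 were higher by 4.19 ± 0.83 and 4.08 ± 0.70. STP9 (3.84 ± 0.16) and QQS (-4.59 ± 0.29) again separated the genotypes.

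Of 15 salicylic acid genes 3 were higher, CBP60G (2.86 ± 0.44), WRKY70 (1.94 ± 0.40) and FMO1 (1.86 ± 0.31), and 9 over the list alone (camera adjusted p = 6.84e-09, or 0.344 with an estimated correlation). GSTF7 and GSTU10 [AT1G74590], at 2.68 ± 0.56 and 1.83 ± 0.34, were the 2 of 16 in their list (5 over the list alone), PUB23 the 1 of 25 genes of pattern perception (12 over the list alone) and CYP81F2 the 1 of 17 pattern-induced markers (8 over the list alone). These 3 lists were called higher (adjusted p = 1.39e-05, 5.9e-09 and 1.82e-08), each with an adjusted p of 0.364 with an estimated correlation. The ethylene list was also called (median 0.77, adjusted p = 0.000124, or 0.364 with an estimated correlation), as were the jasmonate (0.29), phenylpropanoid (0.56) and Pep1 precursor (0.43) lists, with 0 members passing in each of these 4 (over the list alone 4 ethylene and 2 Pep1 precursor genes were higher, and 0 in the others). With an estimated correlation these last 3 had adjusted p values of 0.474, 0.474 and 0.395. Of 13 antimicrobial genes the chitinase gene CHI was higher, by 2.49 ± 0.38 (2 over the list alone), and the list was not called (median 0.07, adjusted p = 0.0906). Cell division genes and splicing factors were called lower (medians -0.18 and -0.15, adjusted p = 0.0121 and 0.00314), with 0 passing in each (2 cell division genes lower over the list alone) and an adjusted p of 0.474 with an estimated correlation for both. Root markers were lower as a list (median -0.69, camera adjusted p = 0.00134, or 0.344 with an estimated correlation), with 2 of 11 passing and 4 over the list alone. The 2 were PRP3 [AT3G62680], a cell wall protein of root hairs (-1.71 ± 0.34), and PYK10 [AT3G09260], a root beta-glucosidase at 876 ± 78.2 FPKM in wild type and 383 ± 50.8 in irr. RHS13, HRGP1 [AT3G54590] and AT3G54580 were lower by values of -2.42 ± 0.32, -2.35 ± 0.37 and -2.14 ± 0.37.

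With Pep1, 278 genes differed between genotypes, 212 higher and 66 lower in irr, and 190 by at least 1 on the log2 scale. The count was 15 by voom on recovered reads, a setting chosen after seeing the data, and 18 in a fit of only the 2 groups. It was 82 with the replicate number as a block, 139 without an expression filter and 145 at a mean of at least 5 FPKM. Quantile normalization gave 434 genes and quality weights 1821. Of these and the genes called under water, 102 were higher and 18 lower in both, against 6.27 and 0.635 for independent lists. In opposite ways went 0. These comparisons share no library but use the shared estimate of the spread, which may by itself raise the overlap. The count was 47, 38 and 24 without WT Pep1 replicates 1, 2 and 3, and 33, 34 and 1646 without irr Pep1 replicates 1, 2 and 3. It was 146 without WT water replicate 1 and 164 without irr water replicate 1.

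**Figure D2:**
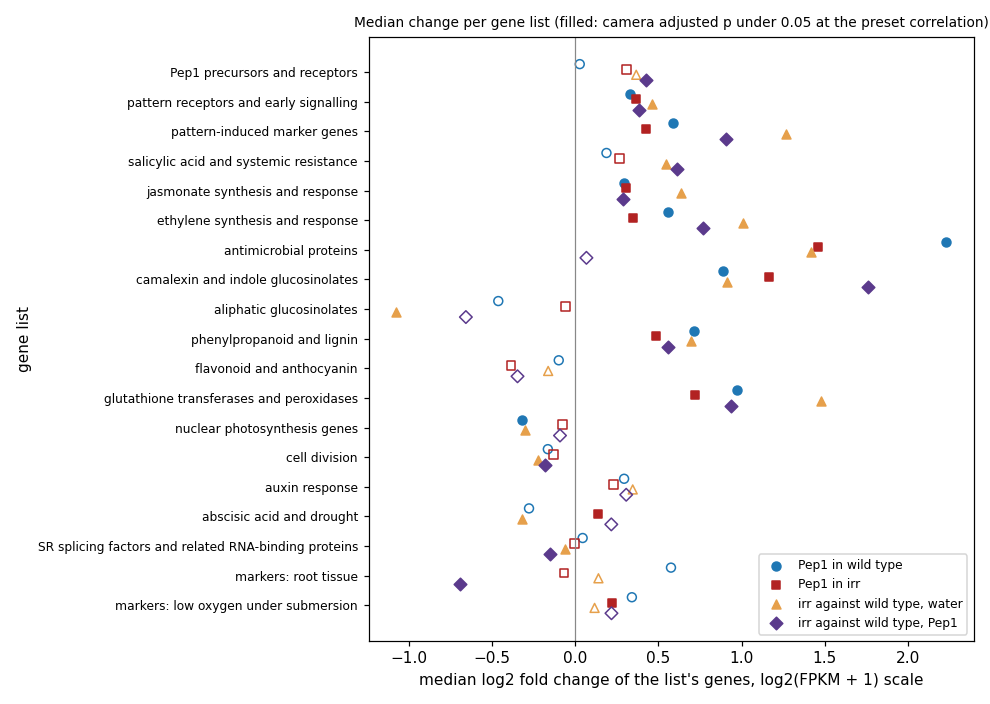
Median log2 fold change (horizontal axis, log2(FPKM + 1) scale) of the genes of each of the 19 lists (vertical axis) in the 4 comparisons, with filled symbols for a camera adjusted p under 0.05 at the preset correlation and open symbols for the rest. The antimicrobial list had its highest median, 2.23, for Pep1 in wild type, and the camalexin and indole list its highest, 1.76, between genotypes with Pep1.

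The last comparison asked whether Pep1 acts differently in the 2 genotypes. No gene passed the interaction test (limma, lowest adjusted p = 0.233, with 1219 at an unadjusted p under 0.05, and 0 by voom on recovered reads, with 1161 at an unadjusted p under 0.05). The 5 genes with the smallest p, none of which passed, were RHS13 (-2.98 ± 0.45), AT4G24130 (1.27 ± 0.20), GATA4 [AT3G60530] (-1.14 ± 0.18), RUP1 [AT5G52250] (-0.72 ± 0.12) and BCCP2 [AT5G15530] (-0.81 ± 0.14). Pep1 fold changes in wild type and irr, which share no library, correlated across 18177 genes with a Pearson r of 0.593 and a Spearman rho of 0.532, where genes are not independent replicates. Of the genes called in each, 68 rose in both and 78 fell in both, against 2.85 and 3.05 for independent lists. In opposite ways went 0. Both comparisons use the shared estimate of the spread, which may by itself raise the overlap. The lists of pattern perception (median -0.03), flavonoids (-0.15) and cell division (-0.05) had negative medians and means and a camera direction of higher in the interaction, and none was called. Among 177 genes that passed for the mean Pep1 effect of both genotypes and rose by at least 1 on the log2 scale, the median was 1.42 in wild type and 1.35 in irr, and the median interaction was -0.29 (fry, adjusted p = 0.658). Among 51 that fell by at least 1, the medians were -1.38 and -1.22, and the median interaction was 0.09 (fry, adjusted p = 0.658). Over all 1109 genes that rose and 991 that fell by the mean effect, the median interaction was -0.12 and 0.0056. Without irr Pep1 replicate 3 the median interaction of the genes rising by at least 1 was 0.40 and 7 genes passed the interaction test, and without WT water replicate 3 it was 1 gene.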

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

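The interaction tests, the gene lists and the leaving out of single libraries were planned, and the test on held-out water libraries was set before its result was seen. The other tests in this part, and the use of the left-out library and the low-oxygen list to weigh explanations, were chosen after the results were seen. The response to Pep1 differed between genotypes for 5 of 19 lists by camera on the interaction. The median interaction was -1.12 for antimicrobial proteins (medians 2.23 in wild type and 1.46 in irr, adjusted p = 0.00412), 0.27 for camalexin and indole glucosinolates (0.89 and 1.17, adjusted p = 0.0052) and 0.23 for photosynthesis genes (-0.32 and -0.08, adjusted p = 1.13e-05). It was 0.54 for abscisic acid genes (-0.28 and 0.14, adjusted p = 7.85e-05) and -0.55 for root markers (0.58 and -0.07, adjusted p = 0.00058). With an estimated correlation the adjusted p values were 0.826, 0.959, 0.959, 0.681 and 0.58, so 0 lists were called. Without irr Pep1 replicate 3, 2 lists were called, and without irr Pep1 replicate 2 there were 8. Between genotypes the antimicrobial list had a median of 1.42 under water and 0.07 with Pep1, so at the list median its smaller rise in irr started from a higher level. CHI, PR4 and TI1 were higher in every irr water library than in any wild-type one. PDF1.2B and PDF1.2A were not higher in irr water replicate 1, at 0.297 and 0 FPKM. They stood at 3.35 and 3.67 FPKM in replicate 2 and at 7.04 and 11.6 in replicate 3.

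Of 108 named genes, 2 had no overlap between water and Pep1 libraries in either genotype, with opposite directions in wild type and irr. In wild type the gap was narrow. RHS13 was at most 2.764 FPKM under water and at least 3.005 with Pep1, and AT4G24130 at least 6.875 and at most 6.724. Both were among the 5 genes named for the smallest interaction p values, so their number is not evidence of a difference. RHS13, a root hair gene, went from 1.99 ± 1.07 to 4.98 ± 2.68 FPKM in wild type and from 3.24 ± 0.828 to 0.0494 ± 0.0428 in irr (SD, n = 3), with an interaction of -2.98, and AT4G24130 had -0.32 and 0.95, with an interaction of 1.27. Neither passed the interaction test over all genes (limma adjusted p = 0.233 for both).

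Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 with the highest count each time, with 630, 362, 713 and 278 genes against a highest other of 0, 94, 0 and 0 for Pep1 in wild type, Pep1 in irr, and irr against wild type under water and with Pep1. For the interaction the real count was 0, so that all 100 of 100 splits drawn reached it says nothing about chance. The highest other split gave 313 genes. It kept the water groups and set WT Pep1 replicate 2 with irr Pep1 replicates 1 and 2 against the 3 other Pep1 libraries. The structure in it is the genotype difference, which its contrast holds by construction (Pearson r of -0.933 with the mean genotype difference across genes, which are not independent replicates).

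Defence lists were higher in the irr water libraries by camera at the preset correlation, while with an estimated correlation the 9 lists had adjusted p values from 0.424 to 0.44. Irr water replicate 3 alone is argued against as the source of the list calls, since 8 of the 9 were still called without it at the preset correlation, the exception being the jasmonate list (median 0.43, adjusted p = 0.0638), although the count of genes that differed went from 713 to 67. A handling difference with low oxygen stays open, as the low-oxygen markers had a median of 0.12 and were not called in either direction. A hypothesis is that part of the Pep1 response may already be present in irr under water. With 200 rises and 200 falls chosen by Pep1 while 1 water library was held out, the held-out genotype difference was higher for the rises in 5 of 6 rotations (median 0.41, from -0.06 to 0.60), the exception being irr water replicate 2, and the test, which asked for 6, leaves it undecided.

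The irr Pep1 libraries were widely spread, and replicate 3 had the lowest Pep1 score of them. A swap with an irr water library is argued against, because on genes chosen by Pep1 in wild type the highest irr water library scored 0.51 and irr Pep1 replicate 3 scored 0.80. A library made wholly from wild-type seedlings is argued against by a genotype score of 0.81, where the wild-type Pep1 libraries scored 0.32 to 0.46. For some wild-type seedlings in that pool, genes higher in irr needed a median share of 64.6% to 79.8% under 4 gene choices. Of 6 genes at least 10-fold apart between genotypes, 3 allowed less (at most 4.97% for QQS, 4.85% for AT4G01980 and 10.6% for STP9, with a floor of 3 reads). The other 3 did not (91.6% for AT5G22555, 81.3% for AT1G13480, and no limit from AT4G19240, listed at 0). The test asked for more than 3 and by that rule stayed undecided. A share of seedlings at the levels of the wild-type Pep1 libraries would, however, act on every gene. Genes that set no low limit then cannot offset those that do. For such seedlings QQS, AT4G01980 and STP9 argue against a share as large as 64.6%, and a share below their limits stays open. This was read after the rule had left the question undecided, and seedlings that differ from irr only at IRR were not considered. Genes lower in irr gave medians of 0.909% to 22.8%, with quartile ranges apart from those of the higher genes under 3 of the 4 choices and overlapping under the broadest, and a difference between wells in exposure to the peptide was not tested.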

How the results depend on the processing

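Voom on recovered reads was chosen after seeing the data, the other settings before. No call of a named gene or list reversed, but the median interactions below changed sign. Counts of changed genes are given in the order Pep1 in wild type, Pep1 in irr, irr against wild type under water and with Pep1 (630, 362, 713 and 278 as reported). Without an expression filter, which tests more genes, they were 407, 194, 267 and 139. Library quality weights gave 2025, 1041 and 1821 for the first, second and last. A fit of only the 2 groups gave 1974, 0 and 18 for the same 3 (limma, 2263 at an unadjusted p under 0.05 for Pep1 in irr). A pseudocount of 5 gave 469 under water, no variance trend 223 for Pep1 in irr, and for irr against wild type with Pep1 a mean of at least 5 FPKM gave 145, quantile normalization 434 and voom 15. A pseudocount of 0.1 gave 1 interaction gene. Apart from fewer libraries or genes, the cause was not tested. The fit of all 12 libraries gives each gene 1 spread for the 4 groups. Median SDs per gene on the log2 scale were 0.12 (WT Pep1), 0.14 (WT water), 0.16 (irr water) and 0.19 (irr Pep1). Contrasts with irr Pep1 thus use a spread drawn partly from tighter groups, and their counts are not on equal terms with that for Pep1 in wild type. Leaving out 1 library gave 105 to 1048, 0 to 1405, 46 to 1431 and 24 to 1646, with 0 to 7 for the interaction; the lowest were without WT water replicate 1, irr water replicate 2, WT water replicate 1 and WT Pep1 replicate 3, and the highest without irr Pep1 replicate 3, except under water, where it was irr Pep1 replicate 2.

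The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.523 to 0.194, 2 of 12 pairs were over 0.1, and 2 of 12 libraries correlated best with their own number. The replicate block gave 488, 147, 389 and 82 genes, and 0 for the interaction.

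Lists called by camera numbered 9, 10, 14, 12 and, for the interaction, 5. An estimated correlation gave 0 in all 5, and fry 1, 0, 3, 3 and 0. The interaction gave 2 lists at a mean of at least 5 FPKM. Leaving out 1 library gave 9 to 12, 4 to 11, 12 to 15, 11 to 15 and 2 to 8, with 4 and 6 for Pep1 in irr without irr Pep1 replicate 2 and irr water replicate 2. The median interaction of genes rising with Pep1 was 0.067 with quality weights and -0.53 to 0.40 with 1 library left out, and that of falling genes was -0.049 and -0.026 to 0.36, below 0 without WT water replicate 1 or irr Pep1 replicate 3. The correlation of Pep1 fold changes was 0.658 at a mean of at least 5 FPKM, 0.552 with quality weights, 0.549 with voom and 0.488 to 0.608 with 1 library left out. Over all settings, 210 named gene results gave 4794 values, of which 4097 kept their side of the threshold, 646 fell below it and 51 passed it. For 95 list results, the numbers were 2134, 142 and 75 of 2351.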

Other observations

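Gene families were picked by words in the product names after the data were examined, 19 families in 4 comparisons. The root-marker list test and the tests of single genes were planned. All other tests in this part were chosen after the results were seen. By camera 33 of the 76 tests passed with adjustment over all 76, and 0 passed with an estimated correlation (lowest adjusted p = 0.605), so the families are described rather than called. Some share members with the fixed lists and are not independent of them, 14 of 50 WRKY factors, 4 of 16 chitinases and 2 of 62 class III peroxidases among those named here. Of 299 genes for ribosomal proteins outside the organelles, 26 fell with Pep1 and 0 rose in wild type (median -0.28) and 29 fell and 0 rose in irr (median -0.23), and the medians were -0.33 and -0.26 with library medians made equal. Class III peroxidases had 15 of 62 rising and 0 falling in wild type (median 0.40) and 5 rising and 1 falling in irr (median 0.32). Dirigent proteins, which act in lignan and lignin coupling, had 3 of 13 rising in wild type (median 1.03) and 1 in irr (median 0.51).

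Between genotypes under water, 11 of 50 WRKY transcription factor genes were higher in the libraries labelled irr and 0 lower (median 0.53), as were 5 of 19 berberine bridge enzyme genes (median 1.08) and 4 of 16 chitinase genes (median 0.99). Extensin genes, which encode cell wall proteins, had 6 of 32 higher and 1 lower in irr under water (median 0.36). With Pep1, 5 fell and 1 rose in irr (median -0.46) and 3 fell and 2 rose in wild type (median 0.26), a difference that was not tested. Between genotypes with Pep1, 2 extensin genes were higher and 3 lower in irr (median -0.35). Beside these, the root markers had a median interaction of -0.55 (camera adjusted p = 0.00058, or 0.58 with an estimated correlation), and RHS13 and EXP7 fell in irr. Of 5 root hair genes, 1 fell with Pep1 in irr (median -6.7e-05) and 2 were lower in irr than in wild type with Pep1 (median -0.34). The medians named in these families kept their sign with library medians made equal and after quantile normalization.

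Among the 20 tested genes nearest to AT3G23900 in gene order, 2 differed between genotypes in both treatments, against 0.66% of all genes. They were AT3G23880, higher in irr by 1.58 ± 0.09 under water and 0.86 ± 0.09 with Pep1, and BAM1 [AT3G23920], higher by 0.58 ± 0.10 and 0.72 ± 0.10 (limma adjusted p from 6.28e-06 to 0.0157). Both were named after their values were seen.

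Irr water replicate 3 held 56.5 M reads but had 234 genes with exactly 1 read, where the 11 other libraries had 778 to 1098. Recovery of reads was not tested on simulated genes with so few reads. Deeper sequencing alone is argued against, as the library detected 22168 genes and the next deepest, WT water replicate 1, detected 22827 with 28.6 M reads. Repeated reads of the same molecules may account for it. Thinned to 17.4 M reads, the library held 21715 detected genes and the others 21952 to 22464. No biological explanation was tested, and the molecules behind the reads were not analysed here.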
